A study of Homo sapiens with 19 samples.

How the data were processed

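RNA was sequenced from blood monocytes of 19 patients with chronic myelomonocytic leukaemia (CMML), a blood cancer in which monocytes accumulate. Per the labels' protocols, mononuclear cells were isolated from blood by density centrifugation, CD14 monocytes were kept by negative selection with magnetic beads, and total RNA was extracted with a column kit. The labels place 10 samples in a group with defective apoptosis and 9 in a group with non-defective apoptosis. They do not say how apoptosis was measured. Each sample was taken as 1 patient. Replicate numbers follow the order of deposition and only name a sample, so no pairing was used. The labels give no sequencing batch or date.

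The deposited files hold raw read counts per gene, 1 file per sample, without normalisation, pooling or a header. Per the submitters' processing notes, the genome build was hg19, and cutadapt, a read trimmer, and DESeq2 were named without a role. The versions, the aligner, the counting program, its strand setting and the annotation release are not given in the sources used here. Each file lists 57820 Ensembl gene identifiers with versions, followed by 5 rows of read classes that name no gene. The whole-number totals differ between files, as raw counts do. Without a known strand setting, reads of overlapping genes on opposite strands cannot be told apart. Reads with more than 1 alignment were kept in a class of their own, so genes with near-identical copies could lose counts.

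Symbols and coordinates came from GENCODE release 44 lifted to GRCh37, the same build as hg19, and 55538 of the 57820 identifiers matched it. The rows of Y-linked genes, XIST and TSIX (532 in all) were removed before library sizes were summed, because the samples are patients. The rows that name no gene were removed as well. With the Y-linked genes, XIST and TSIX still included, the gene counts summed to between 19833704 and 40664052 per library, with a median of 31994681. Of all reads in a file, between 36.5% and 67.8% lay in genes, between 11.3% and 42.3% in the class without an annotated feature, between 1.12% and 2.24% in the ambiguous class and between 9.81% and 35.5% in the class aligned at several places. No 2 libraries were duplicates: 0 of 171 pairs had identical values, and the lowest chi-square per gene was 47.24 over 15475 genes with a mean count of at least 10.

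Genes were tested with edgeR 4.0.16 in R 4.3.3. Libraries were scaled with TMM (factors 0.868 to 1.37) and genes with low counts were removed with filterByExpr, which left 14907. The robust quasi-likelihood test compared the defective with the non-defective group, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 51.1%, with 17 residual degrees of freedom. Log2 differences are given as defective minus non-defective, with standard errors derived from the F statistic. Levels in CPM, counts divided by the scaled library size in units of 1e6, were computed here from the deposited counts and are given as mean ± SD.

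Before the data were examined, 34 gene lists were fixed from textbook knowledge, covering apoptosis, MAPK signalling, interferon and stress responses, metabolism, monocyte subsets and other blood cells. Of 537 symbols, 4 were not matched, and 33 lists had at least 3 tested members. The list of eosinophil, basophil and mast cell markers had 2 and was not tested. Lists were tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, then with an estimated correlation and with fry. In addition, the mean log2 CPM of a list's members (prior count 2) was taken as its level in each sample. The group difference of that level was tested by a two-sided exact permutation test over all 92378 regroupings, for which the smallest possible p is 1.08e-05. P-values were adjusted over the 33 lists. Library properties were tested in the same way. The shares of reads outside features and of reads aligned at several places were added to the planned properties and adjusted separately from them.

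The rule for naming genes was also fixed before the data were examined. It took the 12 genes with the smallest p in each direction among those past the threshold, or, where fewer than 5 passed, the 5 with the smallest p. It added all members of the list of study targets and of the anti-apoptotic BCL2 family, and up to 4 members with the smallest p of any other list described. Some genes that the rule takes are not reported here. Sex-linked markers, HLA genes, immunoglobulin and T cell receptor segments, and genes that follow common deletions were never named. The remaining platelet genes that are named (PPBP, PF4, CAVIN2, CLU, NRGN and SPARC) were chosen after their values were seen.

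Alternatives were DESeq2 size factors, upper-quartile scaling, no filter, a filter of CPM of at least 1 in at least 9 samples, the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, a fit that was not robust, 1 surrogate variable from sva 3.50.0, a covariate for markers of other cell types, and leaving out each sample in turn. Another 2 were added after seeing the data: the share of reads without a feature as a covariate, and a fit without the library with the highest such share and the library with the lowest total count.

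The procedure was tested on simulated counts for the comparison of the defective with the non-defective group, with 14907 genes of which 200 were changed. The edgeR test recovered 46% of 50 genes changed 2-fold, 82% at 4-fold, 80% at 8-fold and 90% at 16-fold, with 4 false calls. DESeq2 recovered 167 of the 200 with 33 false calls. Without any changed gene, edgeR made 0 false calls and DESeq2 made 1. The simulated counts of each gene were drawn independently of other genes, and 200 changed genes make the adjusted threshold easier to pass. The shares recovered therefore do not give the power of the real comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.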

Results

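Chronic myelomonocytic leukaemia (CMML) is a blood cancer marked by a persistent excess of monocytes. The 19 libraries came from CD14 monocytes of patients with CMML, 10 labelled as having defective apoptosis and 9 as non-defective. The series title names Cytokine-like protein 1 (CYTL1), a secreted protein, together with MCL1, an anti-apoptotic protein of the BCL2 family, and the MAPK pathway. The comparison of both groups therefore asks which genes differ in monocytes that resist apoptosis, and whether these genes are among them. The total gene count per library was 32766040 ± 5484625 in the defective group (SD, n = 10) and 30074202 ± 4685370 in the non-defective group (SD, n = 9). Among the measured properties of the libraries, the number of genes with a count was 21024 ± 694 against 22241 ± 1613 (exact permutation p = 0.0419, adjusted 0.167). The share of reads outside annotated features, which was not among the planned properties, was 17.5% ± 4.65 against 24.2% ± 9.08 (exact permutation p = 0.0513, adjusted 0.103 over the added properties alone).

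Genes of platelets and their precursor, the megakaryocyte, were lower in the defective group. The clearest was ITGA2B (ENSG00000005961.13, chromosome 17, 42449548 to 42467017, GRCh37), which encodes the integrin chain that pairs with the product of ITGB3 to form the platelet fibrinogen receptor. Its level was 1.03 ± 0.684 CPM in defective samples (SD, n = 10) against 12.1 ± 16 CPM in non-defective samples (SD, n = 9), a log2 difference of -3.56 (SE 0.562, edgeR adjusted p = 0.0411). All 10 defective samples lay below the non-defective median. ITGA2B was the only gene of the 14907 tested that passed the threshold in the edgeR test. The call ended (adjusted p = 0.0669) without the library with the highest share of reads outside features and the library with the lowest total count. In that fit the log2 difference of ITGA2B was -3.64. The call held in 7 of the 19 fits that left out 1 sample. It was also lost with no filter (edgeR adjusted p = 0.162), limma-voom (0.0936), 1 surrogate variable (0.195) and the covariate for reads outside features (0.369).

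The next 4 lower genes by p did not pass with edgeR, and in each of them all 10 defective samples lay below the non-defective median. DESeq2 called all 4 (adjusted p of 0.00082 or less), so these calls depend on the test. MYL9 (ENSG00000101335.5, chromosome 20, 35169900 to 35179850), a myosin light chain of platelets and smooth muscle, differed by -3.36 on the log2 scale (SE 0.585, edgeR adjusted p = 0.0671, limma-voom adjusted p = 0.0420). It rests on few reads, at 0.0786 ± 0.0665 CPM in the defective and 0.846 ± 0.58 CPM in the non-defective group. TUBB1 (ENSG00000101162.3, chromosome 20, 57594484 to 57601709), the tubulin of the platelet rim, differed by -2.94 (SE 0.542, edgeR adjusted p = 0.108). PTK2 (ENSG00000169398.15, chromosome 8, 141667999 to 142012315), which encodes focal adhesion kinase, differed by -2.99 (SE 0.57, edgeR adjusted p = 0.137), from 23.8 ± 19.8 CPM in the non-defective group to 3.0 ± 2.72 CPM. ITGB3 (ENSG00000259207.3, chromosome 17) differed by -4.03 (SE 0.80, edgeR adjusted p = 0.166). TUBB1, MYL9, PTK2 and ITGB3 each overlap another annotated gene on the opposite strand, and the strand setting of the counts is unknown.

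Of the 13 tested platelet and megakaryocyte markers, 10 were lower and 3 higher, with a median log2 difference of -2.13. With edgeR 1 of them was called over all genes, and adjusted over the list alone 8 were called lower and 1 higher. DESeq2, run without the filter on low counts, called 6 members of the whole list lower over all genes. The per-sample level of the list was 0.44 ± 0.746 log2 CPM in the defective group and 2.11 ± 1.02 log2 CPM in the non-defective group, a difference of -1.67 (SE 0.415, exact permutation p = 0.00039, adjusted 0.0129). It was the only list of 33 whose level passed this test, and 8 of the 10 defective samples lay below the lowest non-defective sample. Without the same pair of libraries the difference was -1.80 (exact permutation p = 0.000247, adjusted 0.00814). Camera called the list lower with the preset correlation, but not with an estimated correlation (adjusted p = 0.113), and fry did not call it for a shared direction (adjusted p = 0.0813) but for change in either direction (adjusted p = 0.0234). Without non-defective replicate 3 the median was -1.34. With the covariate for markers of other cell types the median was -1.41, but that covariate is built in part from this same list. Among the members abundant in platelets, PPBP, a platelet chemokine precursor, was at 4.58 ± 6.57 against 20.5 ± 28.3 CPM and PF4, platelet factor 4, at 2.22 ± 4.15 against 5.48 ± 5.74 CPM. Neither passed over all genes (edgeR adjusted p = 0.660 and 0.740). Leaving out each sample gave log2 differences of -2.96 to -1.34 for PPBP and -2.46 to -0.85 for PF4, the smallest without non-defective replicate 3. CAVIN2, a caveolar protein, had a log2 difference of -2.13. The members that went the other way were CLU, a secreted chaperone, at +1.92 (SE 0.845, and +0.51 with limma-voom), SPARC, a matrix protein, at +0.60 (SE 0.465, and +0.31 without defective replicate 6) and NRGN, a calmodulin-binding protein, at +0.13 (SE 0.194, and +0.037 without non-defective replicate 4).

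**Figure D1:**
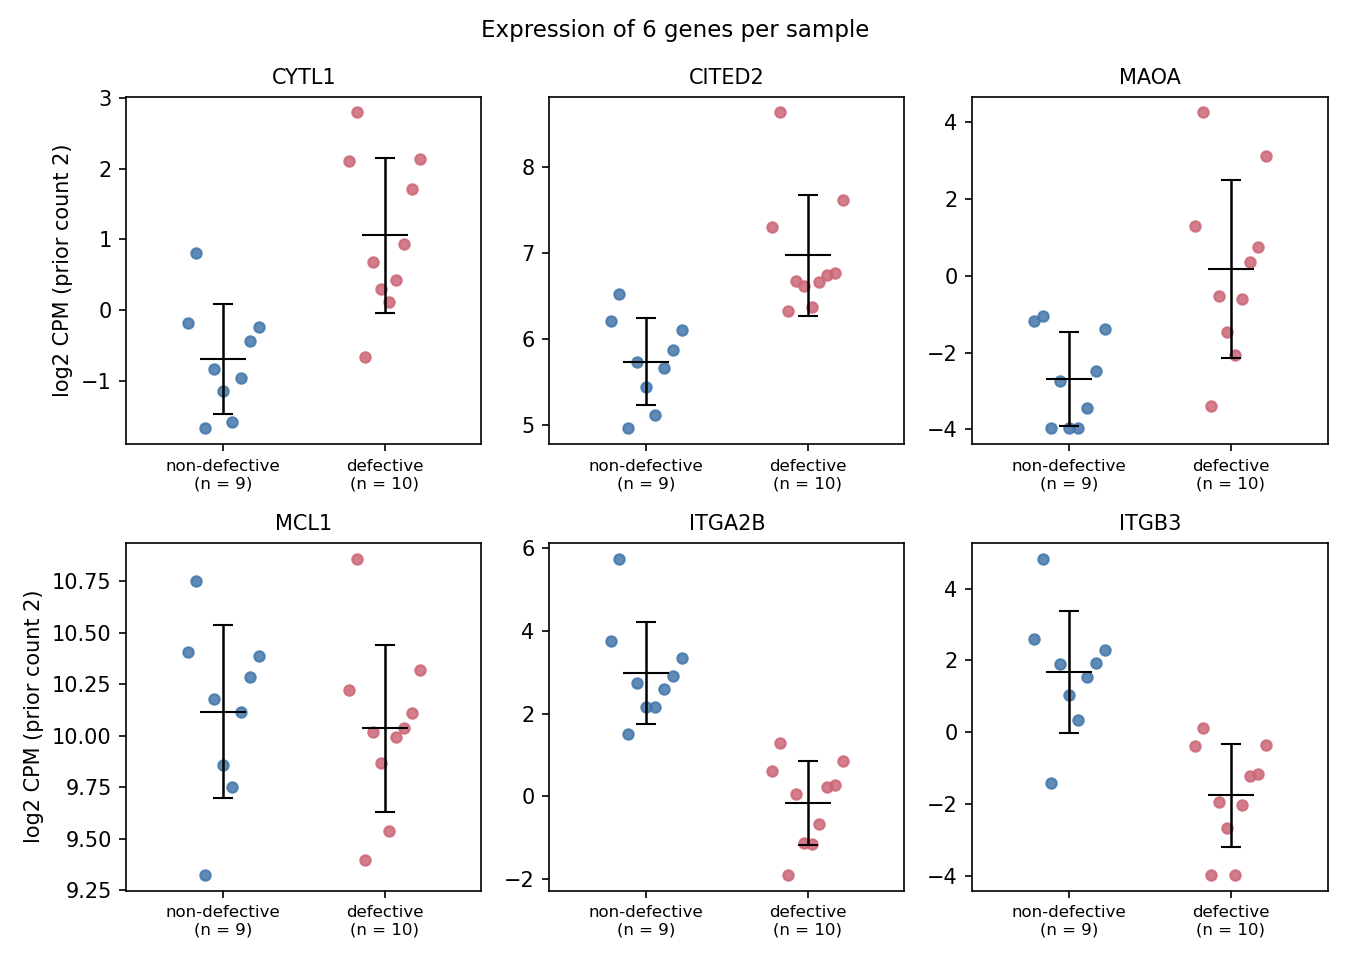
Expression of CYTL1, CITED2, MAOA, MCL1, ITGA2B and ITGB3 as log2 CPM (prior count 2), with 1 dot per sample for 9 non-defective (blue) and 10 defective (red) samples, and a bar for mean ± SD. All 10 defective samples lay below the non-defective median of ITGA2B and above that of CYTL1 and CITED2, while the MCL1 values overlapped.

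Red cell genes were measured at very uneven levels. HBB, a globin chain of adult haemoglobin, was at 11.8 ± 28.3 CPM in the defective group and 406 ± 574 CPM in the non-defective group, and HBA2, a partner globin, at 1.35 ± 3.0 against 53.4 ± 78.3 CPM. All 3 tested erythroid markers, of 16 in the list, were lower. With edgeR 0 passed over all genes and 2 passed adjusted over the list alone. DESeq2 called HBB (adjusted p = 0.0104) and HBA2 (adjusted p = 0.0482) over all genes, so these calls depend on the test. HBA2 has a near-identical copy, so its count is uncertain. The level of the list differed by -2.85 (SE 1.17, exact permutation p = 0.0233, adjusted 0.192). Camera called it lower with the preset correlation, but neither with an estimated correlation (adjusted p = 0.353) nor after limma-voom (adjusted p = 0.0700).

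CYTL1 was higher in the defective group, without passing the threshold over all genes. It is located at chromosome 4, 5016313 to 5021185 (ENSG00000170891.6, GRCh37). Its level was 2.61 ± 2.01 CPM (SD, n = 10) against 0.648 ± 0.44 CPM (SD, n = 9), a log2 difference of +2.0 (SE 0.467, edgeR unadjusted p = 0.000311, adjusted p = 0.385). All 10 defective samples lay above the non-defective median. Adjusted over the list of 8 study targets alone the p was 0.00249, which is not independent evidence because the series title names the gene. DESeq2 called it (adjusted p = 0.00771), and so the call depends on the test.

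The other 4 highest-ranked genes did not pass either. CITED2, a transcriptional co-regulator (ENSG00000164442.8, chromosome 6, 139692944 to 139695785), was at 144 ± 96.5 against 56.2 ± 19.6 CPM, a log2 difference of +1.35 (SE 0.29, edgeR adjusted p = 0.305), with 10 of 10 defective samples above the non-defective median. C1RL, a complement-related protease, differed by +0.67 (SE 0.159, edgeR adjusted p = 0.385), again with 10 of 10 samples above. C1RL and CITED2 each overlap an antisense gene. MAOA (ENSG00000189221.5, chromosome X, 43514155 to 43606064), the monoamine oxidase that degrades serotonin, differed by +4.51 (SE 1.08, edgeR adjusted p = 0.414), from 0.149 ± 0.173 to 3.45 ± 6.02 CPM, with 9 of 10 samples above. The MAOA medians were only 0.919 CPM (defective) and 0.0857 CPM (non-defective). MAOA passed the filter on low counts in 12 of the 19 fits that left out 1 sample. EIF2S3B differed by +2.60 (SE 0.674), but it is a copy of the translation factor gene EIF2S3, so its reads are uncertain. The edgeR test called 0 higher genes, while 520 were higher and 590 lower at an unadjusted p under 0.05. That made 1110 in all, where 745 would be expected by chance on average. How widely such a count varies by chance among correlated genes was not measured. The count also depended on the setting. The share of reads outside features as a covariate gave 429 genes. Leaving out 1 sample gave between 773 (without defective replicate 4) and 1732 (without defective replicate 7). DESeq2 called 6 higher genes, among them CYTL1, CITED2, MAOA and EIF2S3B, and 32 lower genes, of which 6 were platelet markers.

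The counts are of RNA, so protein amounts and the activity of the MAPK pathway were not measured. MCL1 RNA was abundant in both groups and did not differ detectably. Its level was 1089 ± 327 CPM in the defective group and 1151 ± 319 CPM in the non-defective group, a log2 difference of -0.08 (SE 0.188). Among the MAPK genes of the study targets, MAP2K2, which encodes MEK2, was at +0.27 (SE 0.132) with 9 of 10 defective samples above the non-defective median, and MAPK14, which encodes p38 alpha, was at -0.30 (SE 0.17). MAPK3 was at +0.18 (+0.099 without defective replicate 8) and MAP2K1 at -0.05. CCR2, a chemokine receptor of classical monocytes, was at -0.10 (SE 0.443). Of the 8 study targets, 4 were higher and 4 lower, and CYTL1 was the only one that passed adjusted over the list alone. The level of the list differed by +0.29 (SE 0.109, exact permutation p = 0.0198, adjusted 0.192), and by +0.037 (exact permutation p = 0.746) with the median of the members in place of the mean.

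Genes of the apoptosis machinery showed no called difference. All 5 anti-apoptotic BCL2 family members were slightly lower and 0 passed over all genes or adjusted over the list alone. BCL2L2 was at -0.34 (SE 0.214), BCL2L1 at -0.19 (SE 0.142, and -0.12 without non-defective replicate 5), BCL2A1 at -0.08 (SE 0.524) and BCL2 at -0.05 (SE 0.357). Among the 10 tested pro-apoptotic members 8 were higher and 2 lower, led by BMF at +0.62 (SE 0.362), BAD at +0.29 (SE 0.174) and BBC3, which encodes PUMA, at +0.24 (SE 0.275). Of the 16 caspase and apoptosome genes, 8 were higher and 8 lower. Inflammatory caspases CASP1 and CASP4 were at +0.40 (SE 0.198) and +0.36 (SE 0.163), each with 9 of 10 defective samples above the non-defective median. DIABLO, a mitochondrial antagonist of caspase inhibitors, was at -0.59 (SE 0.237) with 10 of 10 samples below, and CYCS, cytochrome c, was at -0.49 (SE 0.233, and -0.28 without non-defective replicate 9). Among the inhibitors of apoptosis, BIRC6 was at -0.49 (SE 0.177, adjusted over the list alone 0.0657) with 10 of 10 samples below. BIRC3 was at +0.39 and NAIP at +0.48 (+0.23 without defective replicate 2). TNFRSF10D, a decoy receptor for TRAIL, was at -0.64 (-0.37 without non-defective replicate 5) and TNFSF12 at +0.35. The p53 targets AEN and CDKN1A were at -1.30 (SE 0.435, and -0.49 without non-defective replicate 5) and -0.74 (SE 0.428), the latter at -0.0094 with 1 surrogate variable. Without defective replicate 9 BMF was at +0.33, BBC3 at +0.091 and BIRC3 at +0.083. With the share of reads outside features as a covariate BCL2L2 was at -0.067, DIABLO at -0.18 and CASP1 and CASP4 each at +0.17. The levels of these 6 lists differed by between -0.14 and +0.14, with exact permutation p of at least 0.337.

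Genes of the RAS-MAPK cascade itself were even, with 7 of 18 higher and 11 lower, and their list level differed by -0.01 (SE 0.0624, exact permutation p = 0.887). Of 11 tested output and feedback genes of ERK, 9 were lower and 2 higher, with a median of -0.77. The transcription factor gene ETV5 was the only one that passed adjusted over the list alone (log2 -1.92, SE 0.591, adjusted over the list alone 0.0409), but the group medians were 0.984 CPM (defective) and 1.00 CPM (non-defective), with 6 of 10 defective samples below the latter. SPRED2, a feedback inhibitor, was at -1.25 (SE 0.55, and -0.81 without non-defective replicate 9), FOSL1 at -0.78 and IER3 at -0.77. Of the 20 immediate early genes 16 were lower, among them EGR3 at -2.22 (SE 0.808), EGR1 at -1.83 (SE 0.804), NR4A3 at -1.26 (SE 0.499) and NR4A1 at -1.07 (SE 0.485), and 0 passed. Levels of the ERK output and immediate early lists differed by -0.26 (SE 0.341, exact permutation p = 0.442) and -0.28 (SE 0.313, exact permutation p = 0.373). The inflammatory genes PTGS2, CXCL8 and TNF were at -1.71, -1.55 and -0.94 (TNF at -0.61 without non-defective replicate 3), and the level of their list differed by -0.10 (SE 0.432, exact permutation p = 0.812). Without non-defective replicate 7 the median of the ERK output list was -0.21, and ETV5 was at -1.22, FOSL1 at -0.44, EGR3 at -1.27, EGR1 at -0.46, PTGS2 at -0.71 and CXCL8 at -0.24. ETV5 was at -0.91 with limma-voom. With 1 surrogate variable SPRED2 was at -0.49, FOSL1 at -0.17, IER3 at -0.46, NR4A1 at -0.60 and NR4A3 at -0.66. The median CXCL8 level was 193 CPM in the defective and 135 CPM in the non-defective group, and 7 of 10 defective samples lay above the latter.

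All 21 tested interferon-stimulated genes were lower, with a median of -1.12, 0 passed over all genes and 7 passed adjusted over the list alone. IFIT1 was at -1.86 (SE 0.556), IFIT3 at -1.89 (SE 0.641), RSAD2, an antiviral enzyme also called viperin, at -1.58 (SE 0.488) and MX2 at -0.80 (SE 0.269). Without non-defective replicate 7 the median was -0.71 and RSAD2 was at -0.76, and with limma-voom IFIT1 was at -1.15 and IFIT3 at -1.06. MX2 was below the non-defective median in 10 of 10 defective samples. The level of the list was 4.87 ± 0.567 against 5.60 ± 1.29 log2 CPM (exact permutation p = 0.122), and 9 of 10 defective samples lay below the non-defective median. Camera called it lower with the preset correlation and not with an estimated correlation (adjusted p = 0.669).

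All 24 cytosolic ribosomal protein genes were higher, with a median of +0.45, 0 passed over all genes and 17 passed adjusted over the list alone. RPS3 was at 841 ± 197 against 590 ± 159 CPM (log2 +0.51, SE 0.173). RPL4 was at +0.49 (SE 0.179), RPL13 at +0.48 (SE 0.178) and RPS9 at +0.46 (SE 0.167). The level of the list differed by +0.46 (SE 0.17, exact permutation p = 0.0149, adjusted 0.192), with 10 of 10 defective samples above the non-defective median. Camera called it higher with the preset correlation and not with an estimated correlation (adjusted p = 0.353). With the share of reads outside features as a covariate the difference in level was +0.20 (SE 0.127) and these 4 genes were at between +0.21 and +0.28. Nuclear genes of oxidative phosphorylation were higher in 19 of 21 cases, with COX4I1 at +0.36 (SE 0.139) and UQCRH at +0.37 (SE 0.167), and a median of +0.19 (+0.12 without non-defective replicate 4). Camera called them higher with the preset correlation, not with an estimated one (adjusted p = 0.811), and their level differed by +0.20 (SE 0.133, exact permutation p = 0.138). With the share of reads outside features as a covariate their median was -0.026, with COX4I1 at +0.19 and UQCRH at +0.10.

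**Figure D2:**
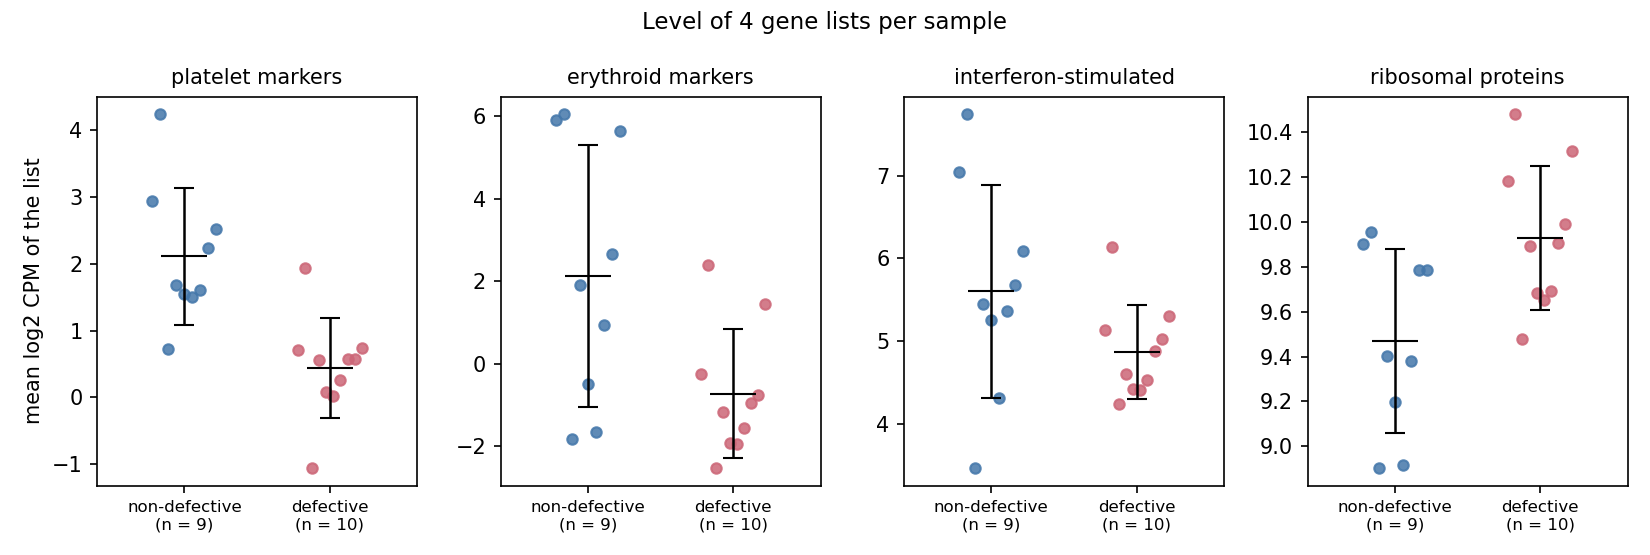
Per-sample level (mean log2 CPM of the members) of platelet and megakaryocyte, erythroid, interferon-stimulated and cytosolic ribosomal protein genes, with 1 dot per sample for 9 non-defective (blue) and 10 defective (red) samples, and a bar for mean ± SD. Platelet markers averaged 0.44 in the defective and 2.11 in the non-defective group, the only 1 of these 4 lists with an adjusted exact permutation p under 0.05.

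The levels of the monocyte marker lists did not differ detectably between the groups. Of 12 classical markers 9 were higher, among them CD163, a haemoglobin scavenger receptor, at +0.63 (SE 0.267), VCAN at +0.44 (SE 0.235) and LYZ at +0.32 (SE 0.186), and the level of the list differed by +0.22 (SE 0.204, exact permutation p = 0.293). With the share of reads outside features as a covariate VCAN was at +0.27 and LYZ at +0.085. For the non-classical list, CDKN1C was at +0.79 (+0.44 without defective replicate 6) and FCGR3A, which encodes CD16, at -0.75, and the level differed by -0.10 (exact permutation p = 0.657). MERTK, a receptor for dying cells on macrophages, was at -0.92 (SE 0.305) with 8 of 10 defective samples below the non-defective median. FLT3, a growth factor receptor of progenitors and dendritic cells, was at +1.56 (SE 0.502, and +0.82 with 1 surrogate variable), and CISH, an inhibitor of STAT5 signalling, was at -0.94 (SE 0.258) with 10 of 10 samples below. Both passed adjusted over their list of myeloid growth factor and survival genes alone (0.0458 and 0.0243) and not over all genes. STAT5B was at +0.26 and STAT3 at +0.22.

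Markers of other blood cells were present at low levels. All 13 NK and cytotoxic cell markers were higher, with a median of +1.31 and 0 passing, led by NKG7 at 38.5 ± 25.2 against 16.4 ± 15.0 CPM (log2 +1.23, SE 0.424), which was above the non-defective median in 10 of 10 defective samples. CST7 was at +1.30 (SE 0.58, and +0.85 without defective replicate 2). GNLY was at +2.35 (SE 0.967). Without defective replicate 10 the median of the list was +0.34 and GNLY was at -0.15. Camera called the list higher with the preset correlation and not with an estimated correlation (adjusted p = 0.811). The call was lost with limma-voom (adjusted p = 0.0904) and with the covariates for reads outside features (0.255) and for other cell types (0.781), and it held in 14 of the 19 fits that left out 1 sample. The NK list level differed by +0.61 (SE 0.702, exact permutation p = 0.412). The levels of the T cell, B cell, dendritic cell and granulocyte lists differed by +0.01, +0.36, +0.08 and -0.14, with exact permutation p of 0.989, 0.316, 0.803 and 0.881. In the granulocyte list OLFM4 and LCN2, both neutrophil granule genes, were at -3.09 (SE 1.23) and -2.24 (SE 1.26). With DESeq2 OLFM4 was at -0.025, and median LCN2 was 4.14 CPM in the defective against 3.03 CPM in the non-defective group. In the B cell list FCER2, a low-affinity IgE receptor, was at +1.69 (SE 1.02), with values of +0.92 without defective replicate 4, +3.19 without non-defective replicate 7 and +0.74 with the share of reads outside features as a covariate. Of 9 stem and progenitor markers 3 were higher and 6 lower. CYTL1 led this list too, while GATA2 and MEIS1, transcription factors of progenitors, were at -3.39 (SE 1.27) and -2.08 (SE 0.894). Without non-defective replicate 4 GATA2 was at -0.45, and without non-defective replicate 1 MEIS1 was at -0.80.

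**Figure D3:**
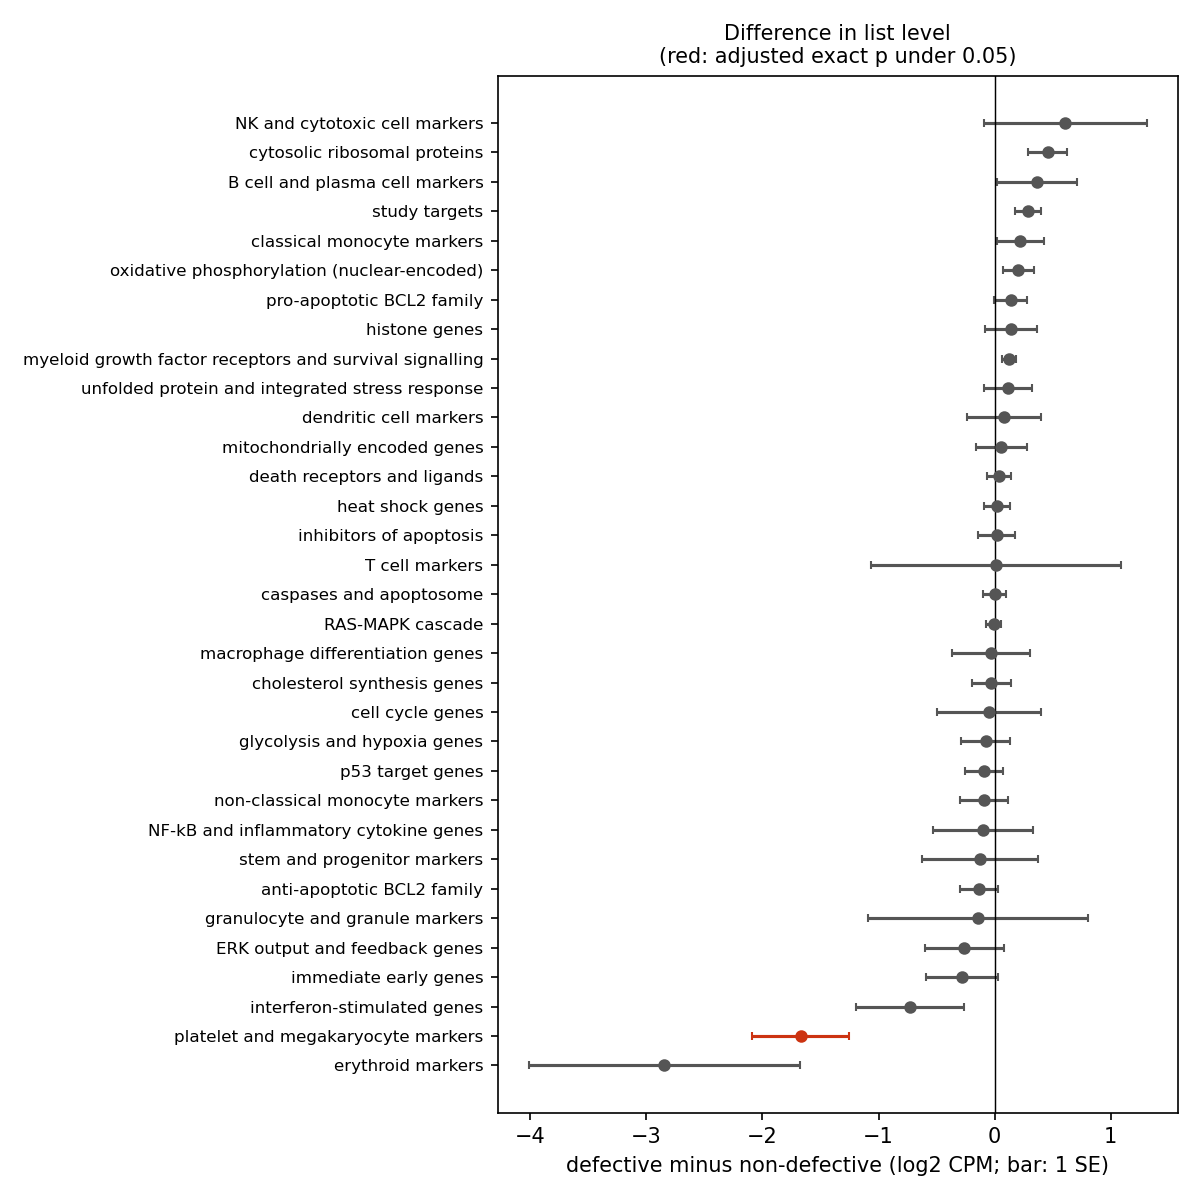
Difference in level between the groups (x axis, defective minus non-defective, log2 CPM) for 33 gene lists (y axis), with a bar of 1 SE and in red the list with an adjusted exact permutation p under 0.05. The red list is that of platelet and megakaryocyte markers at -1.67, and the erythroid list lies lowest at -2.85 with an SE of 1.17.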

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

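The tests of a single library behind the platelet pattern and of progenitor cells behind CYTL1 were chosen after the results they address had been seen. The covariate for reads outside features as an alternative and the fit without a pair of libraries were also chosen after seeing the data. The other tests in this part were set before the result they measure was seen.

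For the lower platelet and megakaryocyte genes, a single library is not the cause, since the difference in list level stayed between -1.407 (without non-defective replicate 3) and -1.845 when each sample was left out. The share of reads outside features is not the cause either, since the difference was -1.879 (SE 0.4545) with that share as a covariate and -1.672 without. RNA from another source, such as platelets carried along with the monocytes, stays open. Within the groups the members varied together, with 49.2% of their variance on the first component. That value was at percentile 99.99 of 10000 random lists matched on expression (median 26.57%). Genes regulated together in the monocytes would also vary together, so the value cannot tell another source from the monocytes. The members that platelets hold abundantly, PPBP and PF4, were at 20.5 and 5.48 CPM in the non-defective group. CLU, NRGN and SPARC, the 3 members that were higher, were at 20.4 CPM or more in both groups. They were picked out after their values were seen, and these levels do not show which cells their RNA came from. Their direction goes against a loss of platelet RNA shared by every member. The negative selection may not remove every platelet, so a difference in carry-over and a difference in the patients' monocytes or blood remain candidate explanations.

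For the higher ribosomal protein genes, the share of a library's reads that aligned at several places does not account for the difference. With that share as a covariate the difference in level was 0.4638 (SE 0.175), against 0.4574 (SE 0.1675) without. The share was 22.7% ± 5.45 in the defective and 20.7% ± 6.56 in the non-defective group, so adjusting for it could change little. Loss of such reads at the ribosomal protein genes themselves was not measured and stays open. With the share of reads outside features as a covariate the difference was 0.2005 (SE 0.1272), so that most of it was gone. A difference in RNA or library quality that shows in that share is therefore consistent with the pattern. The library with the highest such share does not carry it alone, since without it and the library with the lowest total count the difference was 0.438 (exact permutation p = 0.0161). The difference in apoptosis named by the design stays open and untested beside it.

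The higher CYTL1 forms the third pattern. Leaving out each sample in turn gave log2 differences of 1.709 or more, and the share of reads outside features as a covariate gave 2.13 (SE 0.5683), so neither accounts for it. Stem or progenitor cells among the defective samples would carry other markers with them. The 8 other tested markers had a median of -0.2657, with 2 higher and 6 lower, and the largest was +0.2353. Only 9 of the 16 list members were tested, though. Of the lower ones, GATA2 was at -0.45 without non-defective replicate 4 and MEIS1 at -0.80 without non-defective replicate 1. FLT3, a receptor of progenitors that the list lacks, was at +1.56. Such cells are therefore not excluded. As a hypothesis, the difference may belong to the patients with defective apoptosis, but it was found and tested on the same samples and did not pass over all genes with edgeR.

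With edgeR the real split called 1 gene, 3 of 100 splits of the 19 samples, the real one included, called as many, and the highest of the others also called 1. The count met the bound set beforehand, a share under 0.05. The edgeR splits were run with the main setting only, so the share under the alternatives is not known. With 100 splits drawn and a real count no higher than the highest of the others, chance cannot be firmly excluded. The count rests on ITGA2B alone, whose call held in 7 of the 19 fits that left out 1 sample, and any split would match the count of 0 found under 4 of the alternatives. For the gene lists called by camera with the preset correlation chance cannot be excluded. The real split called 6 lists, 81 of the 100 splits called as many, and the highest of the others called 16. In 34 of the random splits the platelet list itself was called. With DESeq2 the real split called 38 genes, the highest of the other 19 splits called 34 and their median was 4.

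Single samples stood apart from their group in 10 of 252 tests, where chance gives about 12.6. The value given with each is the gap to the nearest sample divided by the range of the group. The lowest total gene count among defective samples was 7.297 on the log10 scale, with a gap of 0.592. The highest share of reads aligned at several places among defective samples was 35.53% (95% Wilson interval 35.52% to 35.55%, counting error only), with a gap of 0.477. Gaps for the highest sample were 0.497 for CCR2 and 0.682 for AEN in the non-defective group, and 0.483 for CDKN1A and 0.534 for CXCL8 in the defective group. Gaps for the lowest sample were 0.624 for MX2 and 0.496 for CASP4 in the non-defective group, and 0.503 for CASP4 and 0.555 for TNFSF12 in the defective group.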

How the results depend on the processing

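No paired analysis was possible because each sample was taken as a different patient and the replicate numbers come from the order of deposition. The alternatives with reads outside features as a covariate and without the 2 libraries that stand apart were chosen after seeing the data. The platelet list level was the only list called by the exact permutation test under the main setting, with the median of the members, with a prior count of 0.5 and without those 2 libraries. Camera called between 5 and 8 lists under the alternatives. CYTL1 stayed higher under every alternative run and passed only with DESeq2. With its 10 alternatives that keep all samples, ITGA2B stayed lower and lost its call with no filter, limma-voom, 1 surrogate variable and the covariate for reads outside features. The number of lower genes was 0 with no filter on low counts, with 1 surrogate variable, with the covariate for reads outside features and without the 2 libraries, and 32 with DESeq2, which also called 6 higher genes. With no filter, 35477 genes were adjusted for in place of 14907. Leaving out each sample in turn gave between 0 and 4 lower genes and 0 higher genes. ITGA2B kept its call without defective replicates 2 and 9 or non-defective replicates 2, 3, 4, 8 and 9, and lost it without each of the others (adjusted p 0.0209 to 0.122 over all 19 fits).

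The following log2 differences changed direction, and the cause was not tested. With DESeq2, GNLY was at -0.17. With limma-voom, CCR2 was at 0.46, MAP2K1 at 0.12 and BCL2A1 at 0.15. With 1 surrogate variable, MCL1 was at 0.015 and BCL2A1 at 0.14. With the covariate for other cell types, which is built in part from the NK list, the median of that list was -0.50, BCL2A1 was at 0.18 and GNLY at -0.40. With the covariate for reads outside features, the median of the oxidative phosphorylation list was -0.026, MCL1 was at 0.056 and GATA2 at 1.15. Without the 2 libraries BCL2 was at 0.11. Leaving out each sample gave ranges of -0.17 to 0.18 for BCL2, -0.16 to 0.036 for MAP2K1, -0.43 to 0.19 for BCL2A1, -0.20 to 0.014 for MCL1, -0.27 to 0.64 for CCR2 (positive without non-defective replicate 8) and -0.15 to 2.71 for GNLY. CYTL1, at 0.648 CPM in the non-defective group, and other genes near 1 CPM rest on few reads. Other differences in list level also moved, with none called. With the median of the members the granulocyte list was at 0.39, the dendritic cell list at 0.40, the non-classical list at 0.16, the immediate early list at -0.094 and the NK list at 0.38, and without the 2 libraries the stem and progenitor list was at 0.22. MAP2K2, MAPK3, BAD, BBC3 and STAT3 were closer to 0 with the covariate for reads outside features.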

Other observations

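The tests of both lists below were chosen after the highest-ranked genes had been seen.

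Genes of glycolysis and hypoxia were split, with 10 of 20 higher and 10 lower, although the examples with the smallest p were lower. HK2, the first enzyme of glycolysis, had a log2 difference of -1.08 (SE 0.43) and SLC2A3, a glucose transporter, had -1.23 (SE 0.559), but without non-defective replicate 9 they were at -0.38 and -0.58. The level of the list differed by -0.08 (SE 0.208, exact permutation p = 0.708). Of 19 cell cycle genes 16 were lower and 0 passed, with TOP2A, a DNA topoisomerase of dividing cells, at -0.65 (SE 0.428, and -0.17 without non-defective replicate 7), and the level of the list differed by -0.05 (SE 0.449, exact permutation p = 0.92). In the list of the unfolded protein and integrated stress response, PDIA4, a disulfide isomerase, was at +0.35 (SE 0.151, and +0.13 with the share of reads outside features as a covariate) and above the non-defective median in 10 of 10 defective samples, while the level of the list differed by +0.12 (SE 0.205, exact permutation p = 0.573). The levels of the heat shock, mitochondrially encoded, cholesterol synthesis, histone and macrophage lists differed by +0.02, +0.06, -0.03, +0.14 and -0.03, with exact permutation p of 0.863, 0.803, 0.862, 0.55 and 0.934. The level of the myeloid growth factor and survival list differed by +0.12 (SE 0.0605, exact permutation p = 0.0622, adjusted 0.411) and that of the stem and progenitor list by -0.13 (SE 0.499, exact permutation p = 0.802).

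MAOA and CITED2 ranked among the highest genes, and both can be induced in monocytes by outside signals. As a hypothesis, exposure to glucocorticoids may have differed between the groups. Of the other genes known to be induced by glucocorticoids, 12 were tested as a list, with a median log2 difference of +0.58. Camera called it higher with the preset correlation (adjusted p = 0.000114) and not with an estimated correlation (adjusted p = 0.1839). Its level differed by +0.49 (SE 0.347, exact permutation p = 0.178), and by +0.68 (exact permutation p = 0.0476, adjusted 0.0953) with the median of the members in place of the mean. A second hypothesis is exposure to interleukin-4, which also induces MAOA in monocytes. A list of 8 tested genes induced by interleukin-4, without MAOA, had a median of +0.09 and an adjusted p of 0.3898 with the preset and 0.5318 with an estimated correlation, and its level differed by +0.21 (SE 0.29, exact permutation p = 0.479). Neither list passed with an estimated correlation, the test set for it, and the values leave both hypotheses open.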
